A study of Homo sapiens with 2 samples.

How the data were processed

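RNA of human HaCaT keratinocytes, an immortalized skin cell line, was measured on 2 arrays of 2 colours each. Per the labels, the HaCaT array held cells passaged 50 times without arsenite (0 µM), and the HaCaT-T array held cells kept in 1 µM sodium arsenite for the same 50 passages of 72 h, about 5 months, after which they were termed transformed. Per the labels' protocols, total RNA was immunoprecipitated with an antibody against N6-methyladenosine (m6A). RNA eluted from the beads (IP) was labelled with Cy5 and RNA left in the supernatant with Cy3, with no dye swap. The description label of the unexposed sample uses the name HaCaT-T in passing, whereas its title, treatment label and column header give unexposed HaCaT, and it was used as HaCaT.

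The scanner output of each array gave intensity values, and per the file headers these were made with Agilent Feature Extraction 11.0.1.1 (protocol GE2_1100_Jul11), which subtracted background, detrended the signal and normalized the dyes within each array (linear and lowess). The LogRatio column is log10 of Cy5 over Cy3 processed intensity per the file headers, and was not used for the comparisons. The authors also deposited a log2 table of 35358 probes. For its probes with a single spot, each column was the log2 processed signal plus 1 constant, to within 5.02e-10, with constants of -11.36 (HaCaT IP), -11.03 (HaCaT supernatant), -11.20 (HaCaT-T IP) and -11.15 (HaCaT-T supernatant). What the constants stand for is not given in the sources used here. The column medians were -3.08 for HaCaT IP, -2.76 for HaCaT supernatant, -3.03 for HaCaT-T IP and -3.00 for HaCaT-T supernatant. The constants alone moved the ratio change between the arrays by 0.28 on the log2 scale, so the authors' zero for the m6A ratio lies away from the one used here.

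Each array had 62976 spots. Of the spots of gene type, 60991 in all, 1217 were left out because the software had marked them as non-uniform in a channel of either array, and no spot was saturated. Spots of 1 probe were averaged, which gave 59388 probes. Most had 1 spot and a maker's ID only. A set of 50 probes, each printed 10 times, carried RefSeq accessions, and all 50 matched a symbol in a RefSeq gene table (GRCh38.p14), used for names only. The array design names hg19, so no positions are given. The probes without an accession stay unnamed here.

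The m6A ratio was log2 of processed IP over supernatant signal, centred on each array's median over probes well above background in both channels of both arrays. RNA abundance was log2 of the sum of IP and supernatant signals minus each array's 75th percentile, over probes well above background in at least 1 channel of each array. A probe with several spots counted as well above background when over 50% of its spots were. This scaling left the median abundance change at 0.16, and abundance changes of single genes are given relative to that median. Both changes are HaCaT-T minus HaCaT. The global ratio was taken on background-subtracted signals before dye normalization. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

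With 1 array per group there was no test and no p-value, and a change of 2-fold (1 on the log2 scale) was called large by size alone. The ± beside a named gene is a technical standard error over its spots on these arrays and holds no spread between cultures. The number of arrays limits the precision. Before the data were examined, 29 gene lists and a rule for naming genes were fixed. The rule took, for each comparison, the 8 highest and 8 lowest changes among detected named genes in their brighter part, split at the median, with the same sign after normexp and loess (m6A ratio) or quantile normalization (abundance), plus 9 genes whatever their size and up to 4 members of each list. None of those 9 genes, among them METTL3, METTL14, WTAP, FTO and ALKBH5, could be assigned to a probe. The rule left 9 genes for the m6A ratio and 22 for abundance. Genes outside the rule and the lists are named with the remark that they were chosen after their values were seen. A list's median was set against 10000 random probe lists matched on brightness.

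Alternatives included normexp background correction (limma, offset 50, on median spot signals) with loess or median centring, quantile normalization and no centring. Others were scaling to control spots named after ERCC spike-ins, each channel alone, the authors' deposited log2 values, other filters on dim spots and a 1.5-fold size. Of the ERCC-named probes, 3 were well above background, and whether such RNA was added is not given in the sources used here. The functions were tested on simulated data, with spot noise taken from replicated probes and 200 probes changed. For the m6A ratio (28724 probes), 63 of 65 probes changed 3-fold, 52 of 53 changed 4-fold and 3 of 82 changed 1.5-fold came out at 2-fold or more, as did 259 of 28524 unchanged probes. For abundance (36503 probes), 66 of 66, 53 of 53 and 1 of 81 did, with 4 of 36303 unchanged probes. The noise was taken from ratio changes and added to each channel separately. Noise shared by both channels cancels in a ratio and was left out, so the count of unchanged probes for abundance can be too low.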

Results

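The series set arsenite-transformed HaCaT-T keratinocytes against unexposed HaCaT keratinocytes of the same passage number, to compare m6A levels of their RNAs. There was 1 array per cell population, and each array carried IP and supernatant RNA of the same extract. In the IP channel, 54.8% of the 59388 probes were well above background on the HaCaT array and 54.4% on the HaCaT-T array. In the supernatant channel the shares were 62.0% and 61.3%. Every difference below compares 2 cultures without replicates and could not be set against a spread between cultures.

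The first question was whether the m6A ratio of individual RNAs differed. None of the 42 named genes detected in both channels differed by 2-fold. The farthest from 0, EIF5B, a translation initiation factor chosen after its values were seen, was 0.52 ± 0.05 (log2, technical SE over 9 spots per array) higher in HaCaT-T. Of the 9 genes taken by the naming rule, 5 were higher: LOXL2, a lysyl oxidase-like enzyme of the extracellular matrix, by 0.42 ± 0.15; KIF20A, a mitotic kinesin, by 0.38 ± 0.09; DNTTIP2 by 0.35 ± 0.06; DSCC1, part of a clamp loader for sister chromatid cohesion, by 0.27 ± 0.05; and RHOH, a small GTPase best known from blood cells, by 0.26 ± 0.09. RHOH had by far the brightest named probe, and whether it also binds other RNAs was not checked, so its values are uncertain in their gene. POGLUT2, an O-glucosyltransferase, was at -0.24 ± 0.03 and PIMREG, a mitotic regulator, at -0.22 ± 0.06. NMI (-0.02 ± 0.06) and RPAP3 (0.00 ± 0.15) were within their technical error of 0. With normexp and loess EIF5B was at -0.04, RHOH at 0.80, DNTTIP2 at 0.06 and RPAP3 at -0.39.

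The named genes had high m6A ratios on both arrays; ATAD2, SERPIND1 and POLR2A are given here after their values were seen. In HaCaT, 37 of the 42 lay above the array's median, and their median ratio was 3.74-fold above it. ATAD2, a chromatin ATPase, had a centred log2 ratio of 3.55 in HaCaT and 3.88 in HaCaT-T. For RPAP3, a co-chaperone, the values were 3.17 and 3.17, and for ZNF195, a KRAB zinc finger, 3.27 and 3.31. At the other end, SERPIND1, which encodes heparin cofactor II, had -2.21 and -2.57, and POLR2A, the largest subunit of RNA polymerase II, -0.97 and -0.90. Ratios of different probes also hold probe effects, so the order of genes within an array is descriptive. With median centring, 33 of the 42 genes had a higher ratio in HaCaT-T. Their median change of 0.13 stood at percentile 82.2 of matched random lists, within the middle 95% (-0.04 to 0.20). On the authors' deposited values 41 did, and 31 relative to the median of those values. After normexp and loess, 11 did, and 20 kept their sign. Signs of such small changes therefore depended on the background correction and normalization, which were changed jointly here: BRCA1, a gene of homologous recombination repair, was at 0.38 ± 0.10 with median centring and at -0.39 with normexp and loess. The control probes of GAPDH and PGK1, which encode glycolytic enzymes, also had higher ratios, by 0.32 ± 0.05 and 0.29 ± 0.05 for the 3' and 5' ends of GAPDH and by 0.54 ± 0.27 and 0.20 ± 0.16 for those of PGK1.

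Among the fixed lists, 3 had a detected member on the named probes. The proliferation and mitosis list had 3 of its 37 genes on named probes, and its other genes could not be looked up among the unnamed ones. Ratio changes were 0.38 for KIF20A, 0.03 ± 0.04 for CCNA2 (cyclin A2) and 0.02 ± 0.07 for CENPE (a centromere kinesin). Their median of 0.03 stood at percentile 44.0 of matched random lists. BRCA1, the only member of the DNA repair list with a named probe, stood at percentile 82.2, and ZNF195, at 0.04 ± 0.07, at percentile 43.9. The other 26 lists, among them the m6A writers, erasers and readers, NRF2 genes, metallothioneins, keratinocyte differentiation and the markers of other cell types, had no member that could be named.

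Over all 28724 probes detected in both channels, 262 had a ratio higher by 2-fold or more in HaCaT-T and 311 a lower one. The ratios of both arrays correlated across probes at r = 0.94, where probes are not independent replicates. The 2 brighter unnamed probes with the highest changes were ASHG19AP1B10005990411 (2.88) and ASHG19AP1B10826652511 (1.67), and those with the lowest were ASHG19AP1B10006480111 (-1.64) and ASHG19AP1B12281950911 (-1.55). The split differed between settings. On the authors' deposited values, which cover another set of 35290 probes with another zero, 2562 were higher and 573 lower. Over the 28724 probes, with ERCC-named control spots as the centre, set mainly by ERCC-00097_63, 603 were higher and 154 lower. After normexp and loess 124 were higher and 34 lower, and without centring 334 were higher and 267 lower. More were lower after normexp with median centring (32 higher, 52 lower) and without a filter on dim probes (2613 higher, 4043 lower).

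Whether the m6A ratio as a whole differed was read before any centring. The median log2 ratio of background-subtracted IP over supernatant signal was 0.70 in HaCaT and 0.69 in HaCaT-T, a difference of -0.0093. On the authors' deposited values the median ratio was 0.34 higher in HaCaT-T, and the median share of IP in the summed signal was 44.9% in HaCaT and 50.2% in HaCaT-T. A total difference in m6A could not be read from these arrays, since the amount of each RNA put on the array and the scanner gain also set this value.

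The next question was whether RNA abundance differed. Nearly all detected named genes were lower in HaCaT-T: 39 of 43 lay below the median change of all probes, by 2-fold or more for 16 of them. On the 75th percentile scale, without that shift, 8 of the 43 were lower by 2-fold or more and 1 higher. Among the genes taken by the rule, the lowest were BRCA1, 2.91-fold lower (-1.54 ± 0.07, log2), ATAD2, 2.80-fold lower (-1.48 ± 0.07), POGLUT2, 2.78-fold lower (-1.48 ± 0.04), and DSCC1, 2.45-fold lower (-1.29 ± 0.03). BAZ1A, a chromatin remodelling subunit, DTL, an adaptor of a replication-linked ubiquitin ligase, RPAP3 and NOC3L followed at -1.25, -1.24, -1.18 and -1.13. These values rested on 4 to 10 spots per array with technical errors of at most 0.09. Each probe was printed 10 times, and its other spots had been left out as non-uniform. BRCA1, ATAD2 and NOC3L kept 4 spots, POGLUT2 and RPAP3 5, DTL 9, and DSCC1 and BAZ1A 10. The errors cover the kept spots only. The median change of the 43 genes was -0.90, below all 10000 random lists matched on brightness only (median -0.02, middle 95% from -0.26 to 0.20). Much of this drop was shared by unnamed probes of like m6A ratio. Lists of unnamed probes with the nearest ratio and brightness had a median of -0.56 (middle 95% from -0.79 to -0.33), against -0.91 for the 42 genes detected in both channels.

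Several genes of DNA replication, repair and chromosome segregation were among the named genes. The ones outside the rule and the fixed lists were chosen after their values were seen. RAD54B, a recombination gene, was at -1.21 ± 0.03, CHAF1B, a histone chaperone of replicating DNA, at -1.11 ± 0.07, WDHD1, a replication fork protein, at -1.04 ± 0.05, PRIM1, a primase subunit, at -0.94 ± 0.03, and EXO1, an exonuclease, at -0.88 ± 0.05. Of the proliferation and mitosis list, CENPE was at -1.02 ± 0.06 and CCNA2 at -0.88 ± 0.02, whereas KIF20A was at -0.03 ± 0.05. The list's median of -0.88 stood at percentile 4.16 of random lists matched on brightness only. BRCA1 alone stood at percentile 1.55 of single probes matched on brightness, and ZNF195, at -0.51 ± 0.04, at percentile 27.9.

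Few named genes were higher. By the rule these were POLR2A, 1.46-fold higher (0.54 ± 0.04), and LOXL2, at 0.17 ± 0.11. RHOH, from the probe of uncertain gene, was at -0.09 ± 0.04. Without the shift of the median taken off, POLR2A was at 0.70, and at 0.69 under quantile normalization, 0.53 on the authors' deposited values and 0.15 with ERCC-named control spots as the scale. LOXL2 was at 0.33 without that shift and at -0.22 with ERCC-named control spots. The 3 ERCC-named probes behind that scale disagreed, with unscaled total signal changes from -0.08 to 0.94. Outside the rule, SAA4, a serum amyloid A gene chosen after its values were seen, was 13.3-fold higher (3.73 ± 0.07), with 3.85 in the IP signal and 3.43 in the supernatant signal. This value is uncertain in its gene, since SAA1, SAA2 and the readthrough gene SAA2-SAA4 are close relatives or overlap it. SERPIND1, also outside the rule, was 1.51-fold higher (0.60 ± 0.07). The control probes for the 3' and 5' ends of GAPDH were at -0.17 ± 0.02 and -0.22 ± 0.03, and those for PGK1 at -0.20 ± 0.08 (2 spots per array) and -0.25 ± 0.05. Not well above background were 7 named genes: SPP1, COL13A1, CFTR, ZAP70, TCF7, LOX and CD69.

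**Figure D1:**
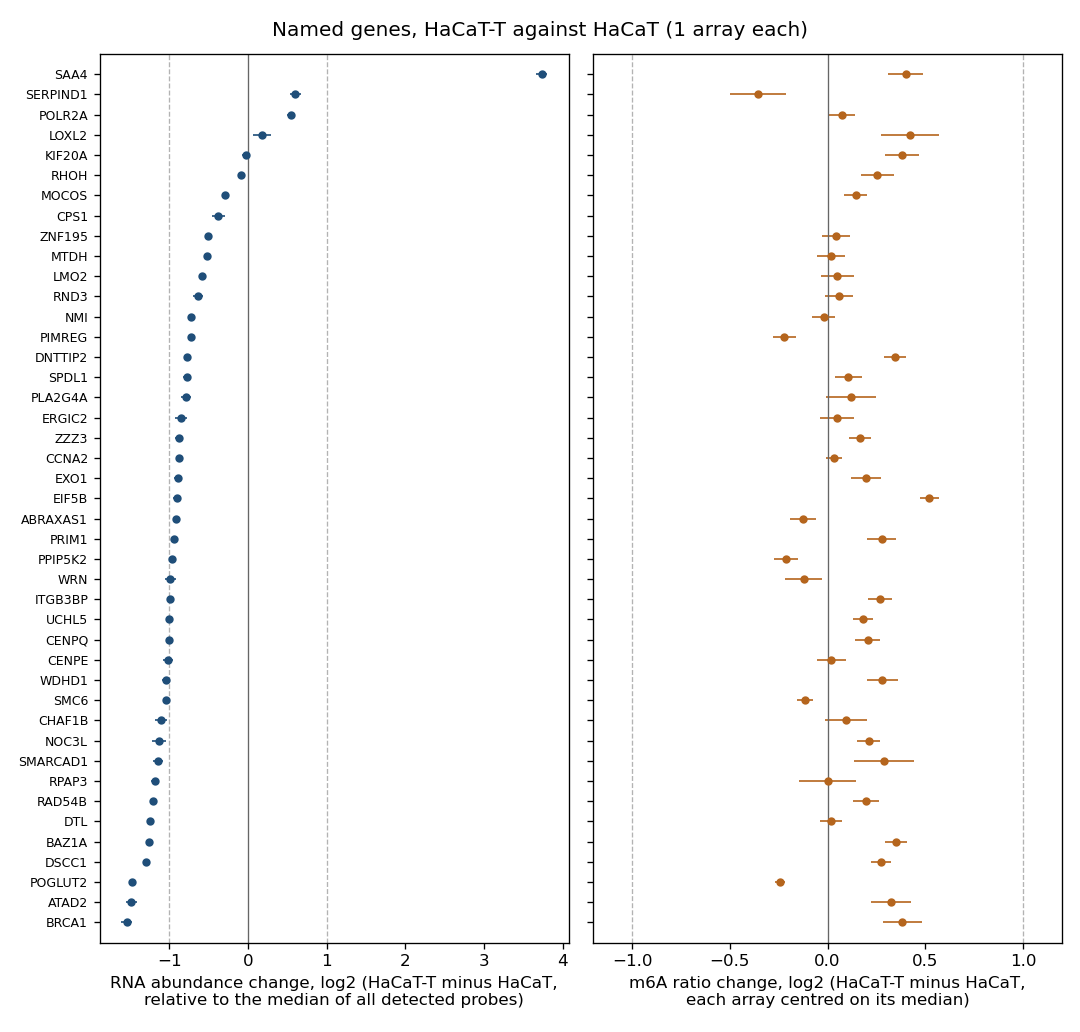
Change of RNA abundance (left, log2, relative to the median of all detected probes) and of the m6A ratio (right, log2, each array centred on its median) from HaCaT to HaCaT-T for the 43 detected named genes, ordered by abundance change. Points are means over a probe's spots on 1 array per group, bars are the technical SE, and dashed lines mark 2-fold. 39 genes lie left of 0 in abundance, while no gene reaches 2-fold in the m6A ratio; CPS1 has no ratio because its supernatant signal in HaCaT-T was not well above background.

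Over all 36503 detected probes, 986 were higher by 2-fold or more in HaCaT-T and 1721 lower when each array was scaled to its 75th percentile. Relative to the median change of 0.16, 495 were higher and 2571 lower. With ERCC-named control spots as the scale, 125 were higher and 6295 lower. That scale is the mean of 3 probes that disagreed, with unscaled total signal changes of -0.08, 0.41 and 0.94. On the authors' deposited values, over their 35290 probes, 745 were higher and 2809 lower. Relative to the median change of 0.16, the 2 brighter unnamed probes with the highest change were ASHG19AP1B10017794011 (13.4-fold higher) and ASHG19AP1B10892494911 (13.2-fold higher). Those with the lowest were ASHG19AP1B10007501711 (8.23-fold lower) and ASHG19AP1B11490351711 (7.28-fold lower). Total signals of both arrays correlated at r = 0.97 across the 28724 probes detected in both channels.

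The last comparison set the changes in m6A ratio and in RNA abundance side by side. Across the 28724 probes, which are not independent replicates, they had Pearson's r of 0.0090 and Spearman's rho of -0.041. The correlation was 0.21 after normexp and loess and -0.34 when abundance was read from the supernatant alone, a signal that also enters the ratio with the opposite sign. EIF5B and BRCA1 combined a lower abundance (-0.90 and -1.54) with a higher centred ratio (0.52 and 0.38), POGLUT2 a lower abundance with a lower ratio, and SAA4 a higher abundance with a ratio change of 0.40 ± 0.09. With normexp and loess, the ratio changes of EIF5B, BRCA1 and SAA4 were -0.04, -0.39 and 0.95.

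Abundance changes were also set against the m6A ratio itself, a comparison chosen after the values were seen. In 10 groups of 2872 or 2873 probes ordered by the mean m6A ratio of both arrays, the median abundance change was highest, at 0.25, in the group with the lowest ratio and lowest, at -0.67, in the group with the highest ratio. In the group with the highest ratio, 613 probes were lower by 2-fold or more and 36 higher, on the 75th percentile scale. In the group with the lowest ratio, 36 were lower and 78 higher. Both channels gave the same order of the outer groups, with medians of 0.22 and -0.64 in the IP signal and of 0.28 and -0.78 in the supernatant signal. Across probes, the m6A ratio and the abundance change had Pearson's r of -0.42 and Spearman's rho of -0.43. Named genes lay on both sides of this trend. Of those with a centred log2 ratio above 3 on both arrays, ATAD2 and RPAP3 were lower in abundance by over 2-fold and ZNF195 by 1.42-fold. Of those below 0 on both, POLR2A and SERPIND1 were higher, while CCNA2 and ITGB3BP, a centromere gene chosen after its values were seen, were at -0.88 and -0.99. The control probes of GAPDH and PGK1 also had ratios below 0 on both arrays, from -1.87 to -0.84 in HaCaT. Their abundance changes, from -0.25 to -0.17, went against the trend.

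**Figure D2:**
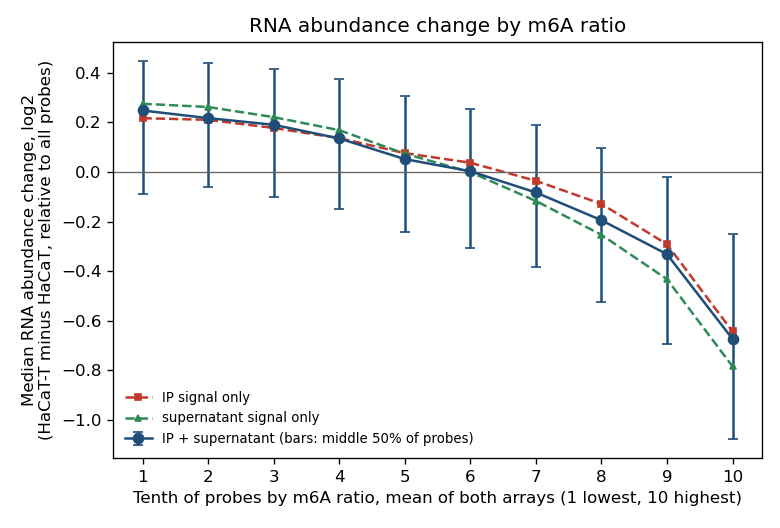
Median RNA abundance change from HaCaT to HaCaT-T (log2, relative to all detected probes) in 10 groups of probes ordered by m6A ratio, for the summed signal (circles, with bars over the middle 50% of probes) and for the IP (squares) and supernatant (triangles) signals alone. The median of the summed signal goes from 0.25 in the group with the lowest ratio to -0.67 in the group with the highest; 1 array per group.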

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

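Of 62 probes outside the probes of gene type that were well above background, among them the GAPDH, PGK1 and ERCC-named probes, 2 had a total signal at least 2-fold higher on the HaCaT-T array than on the HaCaT array and 2 at least 2-fold lower. ASSPINKEIN100003625, a control-type probe with 3 spots per array whose target is not given in the sources used here, was 1.13 higher on the log2 scale. ERCC-00062_278, a control spot named after a spike-in RNA, was 1.07 higher. Both values follow the 75th percentile scaling, and relative to the median change of gene probes they were 0.97 and 0.91. On that relative scale 0 of the 62 probes were higher by 2-fold and 3 were lower, CUST_1_PI418767722 at -1.24, CUST_3_PI418767722 at -1.28 and CUST_9_PI418767722 at -1.05. The other ERCC-named probes well above background moved less in unscaled total signal: ERCC-00097_63 by 0.41 and ERCC-00012_90 by -0.08, against 0.94 for ERCC-00062_278. No explanation was tested for these probes.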

How the results depend on the processing

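No paired analysis was possible because each group has 1 array, so fewer than 2 replicate numbers are shared. Leaving out a replicate was not possible either, and averages over different probes of a gene, or ratio and abundance from different probes, were not run because each named gene has 1 probe. The authors' values for the overall ratio, the scanner error, the median scaling and the values by m6A ratio were chosen after seeing the data. Signal over background limits the ratio counts: of 573 large ratio changes, 192 were below 8 and 194 from 8 to 9 in log2 total signal. The causes of the differences below were not tested, except where the setting itself changes the probes, the size or the zero.

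Of probes with an m6A ratio higher or lower by 2-fold (262 and 311), normexp with loess gave 124 and 34, normexp with median centring 32 and 52, ERCC-named control spots 603 and 154, the authors' deposited values 2562 and 573, no filter on dim probes 2613 and 4043, the brighter probes only 66 and 53, and 1.5-fold as the size 2216 and 1885. No centring, non-uniform spots kept and over 2 times the scanner error stayed within 1.5 times. Of probes with a higher or lower abundance (986 and 1721), normexp gave 165 and 391, ERCC-named control spots 125 and 6295, no filter 2499 and 2668, and 1.5-fold 6235 and 4760. The IP signal alone gave 2192 higher, the brighter probes only 299 higher, median scaling 495 higher, and the authors' values 2809 lower. Quantile normalization and the supernatant signal alone stayed within 1.5 times.

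The overall ratio difference of -0.0093 was 0.15 relative to ERCC-named control spots and 0.34 on the authors' values. On dye-normalized signals, from which the 0.15 also starts, it was 0.04, so it had no settled sign. ERCC-00097_63 had a ratio change of -0.32, against -0.04 for ERCC-00012_90 and 0.03 for ERCC-00062_278. Ratio results relative to ERCC-named control spots therefore rest mainly on ERCC-00097_63. Abundance results on the ERCC-named scale rest on the same 3 probes, whose unscaled total signal changes ranged from -0.08 to 0.94. The correlation of ratio and abundance changes (0.0090) was 0.21 with normexp and loess, -0.042 for the brighter probes and -0.34 with the supernatant signal alone. The gap in abundance change between the 10% of probes with the highest and lowest m6A ratios (-0.92) was -0.63 with normexp, -0.61 in the dimmest and -1.12 in the second brightest of 4 brightness groups. No large abundance change of a named gene or list median changed sign. For the m6A ratio no named gene had a large change. Under normexp and loess, 20 of the 42 named genes kept the sign of their ratio change, and the median of these genes went from 0.13 to -0.13. Of 45 abundance results, 45 moved by less than 1 SD over spots or members under quantile normalization and 1 did with ERCC-named control spots. Of 44 ratio results, 21 did under normexp and loess and 39 with ERCC-named control spots. On the authors' values 39 of all 89 did and 50 moved by more.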

Other observations

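The tests on dye, brightness and the named genes were chosen after the result was seen. Those on the array used for grouping and on spot noise were set down before their values were known. Both came after the patterns they address, the trend and the count of 573, had been seen. RNA abundance in HaCaT-T was lower the higher a probe's m6A ratio was, and 21.3% of the 10% of probes with the highest ratio were lower by 2-fold or more against 1.25% of those with the lowest. The gap between the median changes of these groups was -0.92. It was -0.92 without the named genes too, but these are too few to move it. In simulated arrays without such a trend the gap was -0.0008. Those arrays held only independent spot noise, so they could not show a gap made by dye, brightness or noise shared between channels.

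The tables argue against scaling by brightness and grouping on noisy spots as the whole cause of that trend. Scaling that depends on brightness would leave no gap among probes of like brightness, but the smallest gap in 4 brightness groups was -0.61. Each group is broad, so brightness may still make part of the gap within it. A finer match exists only for unnamed probes resembling the named genes. Their random lists had a median of -0.03 with the nearest brightness and of -0.56 with the nearest ratio and brightness. A bias of 1 dye could not be decided. The gap was -0.86 in the IP signal and -1.06 in the supernatant signal. Dye normalization within each array adjusts the channels to each other, so a bias of 1 dye can enter both. The groups were also cut on the ratio of the dyes, with no dye swap. Grouping on the same noisy spots may also make such a trend, but the gap was -0.94 with groups from the HaCaT array and -0.87 with groups from the HaCaT-T array. RNA integrity and transcript length stay open and were not tested, as does an effect of arsenite transformation on m6A-rich RNAs, since 1 array per group leaves culture, array and treatment together.

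The named genes lay lower in abundance than unnamed probes of like m6A ratio and brightness. Random lists draw probes independently, so their percentiles can be too extreme for genes that change together. Most unnamed probes also have 1 spot, whereas the named genes are averaged over several. For the 42 genes detected in both channels the median change was -0.91, at the 0.13th percentile of random lists of unnamed probes with the nearest ratio and brightness (median -0.56) and at percentile 0 of lists with the nearest brightness alone (median -0.03). A candidate explanation is that 20 of the 43 genes serve DNA replication, repair or division, which would be lower in a slower dividing culture. Their median lay -0.29 ± 0.14 (bootstrap SE) from that of the other 23 genes, which leaves this open: 20 of 20 and 19 of 23 were below the median of all probes. KIF20A, a mitotic gene, was not lower by more than its error.

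Spot noise could account for part of the 573 probes with a 2-fold change of the m6A ratio. From replicated probes of like brightness, 271.2 such probes were expected, or 47.3%. Below 8 (log2 total signal), 182.8 were expected and 192 seen, and from 8 to 9, 76.6 were expected and 194 seen. The spread below 8 came from only 35 replicated spots of 9 probes, so the 182.8 and the 47.3% are imprecise. From 11 to 13, under 1 was expected and 43 were seen, or 0.878% of probes, while 0 of 216 replicated spots deviated that far, which allows a share of up to 1.39%. Rarer spot defects cannot be told apart from true changes there, since most probes have 1 spot.

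The RHOH probe, whose gene is uncertain as said above, had a log2 total signal of 18.3. LMO2 (9.56) and CD69 (4.30, not well above background), genes known from blood cells, were chosen after their values were seen.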
